A study of Sinorhizobium meliloti 1021 with 31 samples.

How the data were processed

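Transcript levels of *Sinorhizobium meliloti* 1021 were measured on 31 Agilent arrays with 2 colours. Per the labels' protocols, cultures grown at 30 °C to an optical density of 0.2 were held for 4.5 h in minimal MOPS medium, which arrests cells in G1, and were then put back into LB/MC, a rich medium. RNA was extracted with the Qiagen RNeasy Plus kit, amplified and labelled with the Ambion Amino Allyl MessageAmp II kit. Cy3 carried the synchronized sample and Cy5 carried 1 unsynchronized culture that served as reference on every array, with no dye swap. The 8 time points have 4 arrays each, except for 160 min with 3, and its replicate 4 is not analysed here. The series' design text calls the replicates biological.

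Spot brightness is held as intensity, per the file headers, in the output of Agilent Feature Extraction 10.5.1.1. The deposited processed intensity values were background-subtracted and dye-normalized by that software, per the file headers. The deposited log10 ratios are red over green within an array. The deposited series table holds log2 ratios for which the submitters' processing notes name limma. From the values, that table is log2 of Cy3 over Cy5: its slope on the scanner's log10 ratio lay between -3.22 and -2.51, column medians lay between -0.02 and 0.04, and its correlation across genes with the ratios used here was 0.880 to 1.00. How it was background-corrected, normalized and averaged over spots stays unknown.

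Each array has 12284 spots for 6142 genes, with 2 spots per gene, and 536 control spots. The fixed plan named mean signals. The files hold no mean signal, so the median spot and background signals were used in their place. Background was corrected with normexp (offset 50, fitted on all spots), and each array was normalized by loess with control spots and spots marked as outliers by the scanner software at weight 0. Outlier spots were then removed, which left 1.39% of values missing, and the spots of a gene were averaged. The losses were concentrated: 61 to 310 genes per array had no value at G1 arrest, and 163 to 525 at 100 min. On every other array at most 51 genes had no value. Some means at G1 arrest and 100 min thus rest on 1 or 2 arrays, such as SMc01305 with 1 at G1 arrest. Genes had to be well above background in either channel on at least 3 arrays, and all 6142 passed. Saturated spots were kept in the fits and counts. A gene with Cy3 dim or saturated on every array of a time point is given as a bound ("at least"), from spot brightness per channel, which is open to dye bias. Where both channels are saturated the ratio is set by the scanner's limit, and no level or bound is given. Values with Cy3 saturated on some arrays may be understated.

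Log2 ratios of Cy3 over Cy5 were fitted with limma 3.58.1 in R 4.3.3, as 8 time-point means with 1 shared estimate of the spread over all arrays. The Benjamini-Hochberg adjusted p threshold was 0.05, tests were two-sided, and all adjusted p values of single genes come from this model. An F-test asked which genes varied over all 8 time points and over the 7 released ones. The contrasts were 40 min and 160 min against G1 arrest, 120 against 40 min, 140 against 60 min, 100 against 80 min, and each time point against the reference. The reference is 1 RNA sample, so tests against it leave out its own spread, and without dye swaps a dye effect of a probe cannot be told from a difference there. Between time points both cancel only where the Cy5 channel is the same on all arrays, which was checked per channel for the 4 contrasts within a slide and not for 40 min against G1 arrest. The number of arrays limits the precision.

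Slides and scans are batches here. The arrays lie on 4 slides scanned on 3 days: 40 with 120 min, 80 with 100 min, G1 arrest with 160 min, and 60 with 140 min. The slides with 80 and 100 min and with G1 arrest and 160 min share a scan day. The earlier time point of each slide is always in row 1 and the later in row 2. So 4 contrasts lie within a slide, and a slide term leaves them unchanged. The contrast of 40 min with G1 arrest lies between 2 slides, where batch and group cannot be told apart by a fit.

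The files give locus tags without gene names: 3297 with the prefix SMc (chromosome), 1284 with SMa (the megaplasmid pSymA) and 1561 with SMb (the megaplasmid pSymB). The gene table used is of *Ensifer adhaerens* Casida A and matched 0 of the tags, so tags are printed as they stand. Before the data were examined, 30 functional lists were written as gene names with a few locus tags from general knowledge, which no table used here checks. Only 3 of them had at least 3 tags: cell cycle regulators (12 tags), cell division (5) and motility regulators (3). A further 5 had 1 or 2 tags: flagella, general stress and nitrogen starvation with 1 each, phosphate starvation and chaperones with 2 each. The chromosome and both megaplasmids were tested as lists too. Lists were tested with camera of limma (preset correlation 0.01, adjusted over the 6 lists of a contrast), on 6013 genes. Camera compares a list with the other genes, and the chromosome and megaplasmids together hold all genes. So opposite calls of these replicons in a contrast are relative to each other and not separate results. The missing values of a gene were filled with its mean at that time point. This understates the spread where values are missing, mainly at G1 arrest and 100 min. Filling was chosen after seeing that only 2 of the 5 cell division tags and 8 of the 12 regulator tags have a value on every array. The regulator SMc00654 has no value at G1 arrest and is left out of the set tests. The means of lists and stretches per array use the same filled values over the tags with a value at every time point and neither channel saturated on every array of any, so that every array averages the same measured tags. The search for arrays apart from the rest uses these means as well. This too was chosen after the data were seen, it decides which arrays stand apart, and it understates the spread where values are missing. Of 6142 genes 5559 have no such saturation. The set tests keep saturated genes, and the same tests without saturated spots, added after the data were seen, leave 10 regulators, 1 cell division tag and 3 motility regulators.

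The rule for named genes was the 10 largest rises and falls with non-overlapping arrays among genes with a symbol, and all members of the 3 lists. No symbols could be matched, so at most 2 tags that rose and 2 that fell are printed per comparison. After the values were seen, it was added that these have values on at least 3 arrays at both time points and are neither dim nor saturated on every array of 1. Stretches of consecutive tags are named as well. They were chosen after their values were seen, as runs in which every tag passed the threshold and changed at least 2-fold in some contrast, so that in the contrast of its choice all tags of a stretch pass by selection. Contrasts that share arrays with that one are not independent of the choice either.

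The fits were tested on simulated log ratios of 6142 genes, drawn independently per gene and without slide effects. Background correction, normalization and saturation were not simulated. For 120 against 40 min, 94 of 100 genes changed by 1 log2 unit and 100 of 100 changed by 2 were recovered, with 10 false calls. For 160 min against G1 arrest the numbers were 87 and 99 of 100, with 16 false calls, and for the F-test over 8 time points 87 and 98 of 100, with 8 false calls. A list shift was simulated only for 120 against 40 min, where the shifted list was called and the others were not. Genes were independent there, so the list test was not tried under correlation between genes. Alternatives changed the background correction, the normalization, the starting values, filters, thresholds, moderation, array weights, blocks and arrays, and left out each replicate in turn. Python 3.11.15 with matplotlib 3.10.9 drew the plots.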

Results

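RNA of *Sinorhizobium meliloti* 1021, a soil bacterium that fixes nitrogen in legume root nodules, was profiled through a synchronized cell cycle. Cells were arrested in G1 in minimal medium and sampled there and 40, 60, 80, 100, 120, 140 and 160 min after release into rich medium. The labels place 40 min at the end of G1 as replication starts, 60 min at replication initiation, 80 to 120 min in S phase, 140 min in late S phase and G2/M, and 160 min in G2/M. There were 4 arrays per time point, and 3 at 160 min. Brightness differed between slides: the median Cy3 signal was 4043 to 8216 on the slides of 40, 60, 120 and 140 min, and 152 to 289 on those of G1 arrest, 80, 100 and 160 min. On the dim slides 58.4% to 86.5% of spots were well above background in Cy5, and 3496 genes were so in both channels on all 31 arrays. On the bright slides strong spots reached the scanner's limit: Cy3 was saturated on every array for 316 genes at 40 min, 317 at 60 min, 405 at 120 min and 357 at 140 min. Correlations across genes between replicates ran from 0.631 at 140 min to 0.980 at 120 min, and no pair of arrays was a copy.

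Over the whole course, the question of the series, most genes differed between time points. Each time point lies on 1 slide, so the F-test counts mix differences between slides with those over time. Of 6013 genes, 5565 varied over the 8 time points, 3376 of them at least 2-fold between their highest and lowest mean. Without G1 arrest, 5007 of 6045 varied, 2029 at least 2-fold. A run of 54 tags, SMc03004 to SMc03057, had its lowest mean log2 ratio to the unsynchronized culture at 40 min, -3.12 ± 0.63 (SD, n = 4), and was at 0.33 ± 0.09 at 120 min and 0.31 ± 0.09 at 140 min (SD, n = 4), over the 26 tags with a value and without saturation at every time point. It holds the 3 motility regulator tags and the flagella tag. At G1 arrest, on a dim slide where the offset shrinks ratios, its mean was -2.07 ± 0.11 (SD, n = 4). A run of 41 tags, SMb20161 to SMb20208, was highest at G1 arrest, 2.95 ± 0.19 (SD, n = 4), and lowest at 160 min, 0.12 ± 0.07 (SD, n = 3), over 29 such tags. A run of 15 tags, SMc01303 to SMc01317, had a median of -3.04 at G1 arrest and of -0.38 at 160 min. At 40, 60, 120 and 140 min at most 3 of its 15 tags were free of saturation, so no level is given there. These runs were picked for changes between some of these samples, so their extremes follow in part from the choice.

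The 10 cell cycle regulators without saturation averaged -1.18 ± 0.20 at 40 min and 0.21 ± 0.04 at 140 min, the lowest and highest of their means (SD, n = 4). Of the 5 cell division tags 4 were saturated on every array of some time point. The motility regulators went from -1.37 ± 0.34 at 40 min to 0.75 ± 0.11 at 120 min. Of the 3376 genes 2963 were free of saturation at every time point, and of these 1077 were highest at G1 arrest, 364 at 40 min, 357 at 60 min, 194 at 80 min, 148 at 100 min, 345 at 120 min, 315 at 140 min and 163 at 160 min. The low counts at 80, 100 and 160 min are all of dim slides, where the offset shrinks ratios. With saturated genes included they were 289, 195 and 219, and the scanner's processed signals raised each of them, as given under processing. So these counts do not give a distribution of peak times free of slide brightness. With slide as a block only the contrasts within slides can be tested jointly, which is a narrower question than the F-tests over all time points. All of these contrasts together gave 4203 genes. Those between released time points gave 2584, which leaves out 160 min and includes 100 against 80 min. Within the dim slides, which share a scan day, 3877 genes varied, and within the bright slides 4217. Both of these counts still compare time points between slides.

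**Figure D1:**
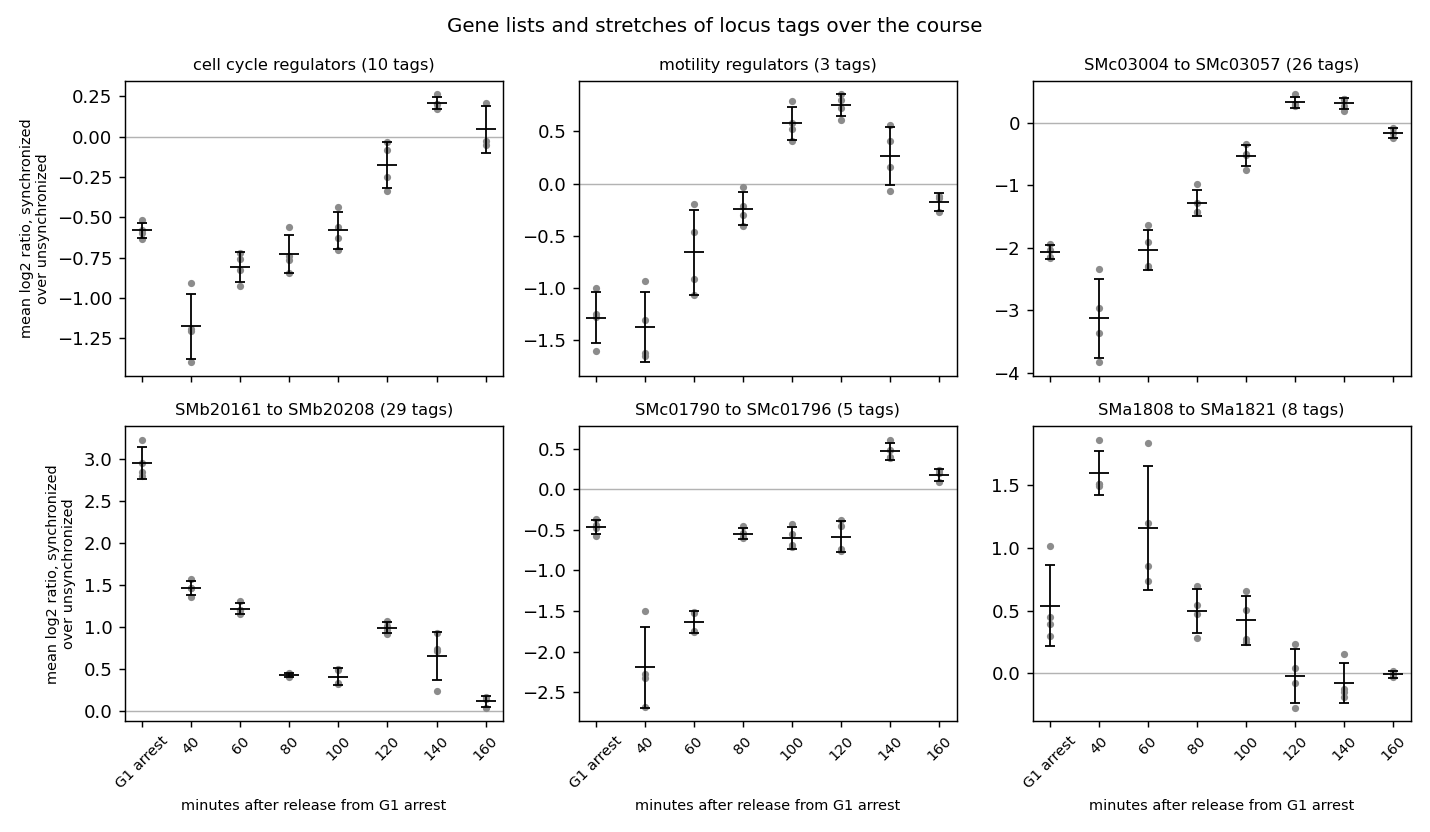
Mean log2 ratio of synchronized to unsynchronized RNA (y axis) at G1 arrest and at each time after release in minutes (x axis), for 2 functional lists and 4 stretches of locus tags. Grey points are single arrays averaged over the tags with a value and without saturation at every time point, and black bars are the mean with its SD; SMc03004 to SMc03057 climbs from -3.12 at 40 min to 0.33 at 120 min, while SMb20161 to SMb20208 falls from 2.95 at G1 arrest.

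Arrested cells were set against the unsynchronized culture, the comparison that the series' design names. The arrest was made by 4.5 h in minimal medium, so effects of that treatment cannot be told from those of G1 here. The stretch SMb20161 to SMb20208 was higher at all 41 tags, with a median log2 ratio of 3.67. It was picked for its fall from these same G1 arrest arrays to 160 min, so this follows in part from the choice. Within it SMb20186 was at 7.98 ± 0.91 (SD, n = 4), or 252-fold, and SMb20204 at 7.43 ± 0.70 (SD, n = 4). SMc03004 to SMc03057 was lower at all 52 tags with a value (median -2.56), and SMc01303 to SMc01317 had a median of -3.04 over 15 tags that are a run picked in this comparison. SMc01506, the tag of the general stress list, was at 3.08 ± 0.12 (SE, n = 4).

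In all, 1995 genes were higher and 2099 lower at arrest, of 6100 tested. Among genes with values on at least 3 of the arrays, the lowest were SMb21175, at -4.87 ± 1.29 (SD, n = 4) with Cy3 well above background on 2 of 4 arrays, and SMc00565, at -4.63 ± 0.10 (SD, n = 3). Of 11 regulators 6 were lower and 1 was higher, SMc00776 at 1.09 ± 0.13 (SE), with the same 6 and 1 adjusted over the list alone. Their set test gave an adjusted p of 0.0727. Of the cell division tags 2 were lower and 0 higher, also when adjusted over the list alone (set test, adjusted p = 0.173). All 3 motility regulators were lower, also when adjusted over the list alone, with SMc03046 at -1.84 ± 0.17 (SE), but the set test gave an adjusted p of 0.0537 (0.0331 without saturated spots). The flagella tag SMc03037 and the phosphate tag SMc02146 had no value at arrest. With outlier spots kept they were at -2.78 ± 0.30 and -5.00 ± 0.47, and the regulator SMc00654 at -1.77 ± 0.23 (SE, adjusted p = 3.08e-09, 1.88e-10 and 8.63e-08). The other phosphate tag, SMc02140, was at -1.81 ± 0.32 (SE), the tags put on the chaperone list, SMc03873 and SMc00646, at 1.16 ± 0.13 and 0.67 ± 0.12, and the nitrogen tag SMc01043 at -0.60 ± 0.09. Whether the tags of the chaperone list code for chaperones was not checked.

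Chromosomal genes were lower at arrest as a set (adjusted p = 7.2e-05, median -0.19), with 1513 lower and 935 higher over all genes, and 1521 and 945 adjusted over the list alone. Genes of pSymB were higher as a set (adjusted p = 0.000356, median 0.11), with 633 higher and 337 lower, and 632 and 332 adjusted over the list alone. For pSymA 427 were higher and 249 lower (418 and 243 adjusted over the list alone; set test, adjusted p = 0.0727). The set tests of the replicons are relative to each other, so these calls of the chromosome and pSymB are not separate results. With median centring in place of loess the chromosome's adjusted p was 0.0755. Restricting the test to genes bright on every array left 34.4% of the called genes higher, against 48.7%.

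After release the later time points were compared with the same reference culture. Its Cy5 signal differed at 949 genes between the 80 and 100 min arrays. This bears on the counts at both times, and on the F-tests, profiles and peak times that include these arrays. The stretch SMb20161 to SMb20208 still held 33 higher tags of 41 at 40 min and 18 at 160 min. At 40 min Cy3 was saturated on every array for 12 of the 41. In SMb20172 it was so at 40, 60 and 120 min, where this tag was at least 17.2-fold, 22.7-fold and 27.3-fold higher. Among genes without saturation and with values on at least 3 arrays, the lowest at 40 min were SMc03025, at -5.35 ± 1.03, and SMc03030, at -4.97 ± 1.05 (SD, n = 4). The number of genes that differed was 4030 at 40 min, 3321 at 60 min, 2625 at 80 min, 2566 at 100 min, 3741 at 120 min, 2454 at 140 min and 1480 at 160 min. At 160 min 691 were higher and 789 lower, and without replicate 2 the count was 962. Median centring raised the counts at 80, 100 and 160 min to 4830, 4271 and 4885.

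At 40 min against G1 arrest, the first step after release, the stretch SMb20161 to SMb20208 fell at 27 of the 29 tags without saturation, with a median of -1.44 on the log2 scale. SMc03004 to SMc03057 fell at 36 of 48 such tags and rose at 3, and SMa1808 to SMa1821 rose at all 8 (median 1.09). SMb20161 to SMb20208 and SMc03004 to SMc03057 were picked in contrasts that share the G1 arrest or the 40 min arrays, which favours these falls. G1 arrest also lies on a dim slide, where the offset shrinks ratios, so low ratios there can look less low than at 40 min. This too favours the fall of SMc03004 to SMc03057, for which no value without the offset is given. Its tag SMc03046 lost the fall with offset 0, as given below. The 8 tags of SMa1808 to SMa1821 also fell at least 2-fold from 40 to 120 min, on the same 40 min arrays. The choice of stretches may thus favour their rise too. SMb21277 rose by 3.72 ± 0.35 (SE, n = 4), with Cy5 well above background on 2 of the 4 G1 arrest arrays, and SMb21275 by 3.64 ± 0.38. SMc02171 fell by 6.88 ± 0.31 (SE, n = 4; adjusted p = 1.02e-16), or 118-fold, and SMc02172 fell by 5.34 ± 0.46 from 3.14 ± 1.88 (SD, n = 4) at arrest. SMc01506 fell by 3.19 ± 0.17. Of the tags put on the chaperone list SMc03873 fell by 1.99 ± 0.18, while the other, SMc00646, was at -0.31 ± 0.16 and did not pass.

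Of 6100 genes 2101 rose and 2164 fell. Among 11 regulators 2 rose and 6 fell, also when adjusted over the list alone: SMc02139 rose by 1.58 ± 0.20 and SMc01167 by 1.18 ± 0.31 (0.37 with median centring, adjusted p = 0.293, and 0.36 in the deposited series values, adjusted p = 0.262), and SMc00059 fell by 2.30 ± 0.35 and SMc00776 fell by 2.11 ± 0.19. Of the cell division tags SMc04296 rose by 1.64 ± 0.14 and 3 fell, SMc01874 the most with -2.10 ± 0.16 (the same 1 and 3 adjusted over the list alone). Neither list stood apart from other genes (camera, adjusted p = 0.483 for both), while fry, which does not compare with other genes, found both lower on balance (adjusted p = 3.14e-05 for regulators and 0.0042 for cell division). Of the motility regulators SMc03015 rose by 0.80 ± 0.19 and SMc03046 fell by 1.11 ± 0.23, also over the list alone, and SMc03016 was at 0.03 ± 0.19. SMc03046 was at 0.36 (adjusted p = 0.353) with the scanner's processed signals, -0.12 (0.748) with offset 0 and -0.48 (0.133) in the deposited series values. The list's mean was -0.09, its median 0.03 and the set test pointed up (adjusted p = 0.984). SMc01043 rose by 0.96 ± 0.13. The phosphate tag SMc02140 was 2.14-fold higher (adjusted p = 0.0308), but 7 of 20 alternatives ended the call, among them median centring (adjusted p = 0.122) and leaving out replicate 1, 2 or 3 of G1 arrest or 1 or 3 of 40 min (adjusted p from 0.0571 to 0.0692). Its log2 change ran from 0.78 with median centring to 2.43 with the scanner's processed signals. SMc02146, SMc00654 and SMc03037 had no value at arrest, and Cy5 was saturated on every array at 40 min.

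Chromosomal genes rose as a set (adjusted p = 0.0222, median 0.15; 1375 rose and 1057 fell, 1381 and 1063 adjusted over the list alone), and those of pSymB fell (adjusted p = 0.0455, median -0.13; 418 rose and 649 fell, 416 and 649 adjusted over the list alone). For pSymA 308 rose and 458 fell (303 and 453 adjusted over the list alone; set test, adjusted p = 0.285). The replicon calls held with an estimated correlation but ended without saturated spots (adjusted p = 0.121 and 0.146), on genes complete on every array (adjusted p = 0.168 for both) and with median centring, where the chromosome pointed down (adjusted p = 0.969) and pSymB gave 0.456. The contrast lies between a bright and a dim slide and also spans the change of medium.

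**Figure D2:**
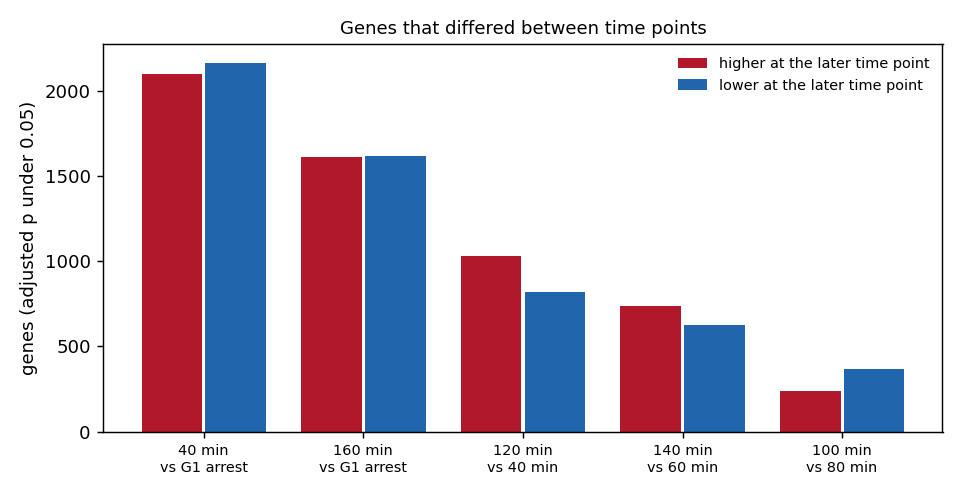
Number of genes (y axis, from 0) past the adjusted p threshold of 0.05 in each contrast between time points (x axis), red for higher and blue for lower at the later time point. The counts run from 2101 higher and 2164 lower at 40 min against G1 arrest to 236 and 366 at 100 against 80 min, where most of the change lay in the Cy5 reference.

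At 160 min, the end of the course, cells differed from G1 arrest in opposite directions at the main stretches. SMc03004 to SMc03057 rose at all 52 tags with a value (median 2.08). SMb20161 to SMb20208, the longest run of tags that fell at least 2-fold here, had a median of -3.18 over its 41 tags, and SMc01303 to SMc01317 one of 2.80 over its 15. In these 2 runs every tag passed because they were picked so. SMb21488 rose by 5.41 ± 0.29 (SE, adjusted p = 6.89e-14), or 42.4-fold, and SMb21487 by 5.04 ± 0.31. SMc00819 went from 6.32 ± 0.41 (SD, n = 4) to -0.68 ± 0.20 (SD, n = 3), or 128-fold lower (adjusted p = 2.35e-14), and SMc02229 fell by 5.71 ± 0.27, with Cy5 well above background on 1 of the 3 arrays of 160 min. SMc01506 fell by 3.10 ± 0.19 and SMc03873 fell by 1.37 ± 0.20.

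Of 6099 genes 1609 rose and 1615 fell (3 arrays against 4), and 2717 passed within the slide alone. All 3 motility regulators rose, with SMc03046 at 1.41 ± 0.25, and 3 of 5 cell division tags, with SMc04296 at 1.74 ± 0.16. Adjusted over the list alone 3 and 5 rose. Of 11 regulators 6 rose and 1 fell, the same adjusted over the list alone: SMc02139 rose by 1.69 ± 0.22, SMc00021 by 1.16 ± 0.23 and SMc02369 by 1.14 ± 0.22, and SMc00776 fell by 1.01 ± 0.20 but was at -0.26 with median centring (adjusted p = 0.257). The cell division set rose (adjusted p = 0.0383), with an adjusted p = 0.146 with an estimated correlation, and 0.36 without saturated spots, which leaves 1 of its tags. Regulators and motility regulators did not pass as sets (adjusted p = 0.0562 and 0.0554; adjusted p = 0.146 and 0.17 with an estimated correlation; 0.049 for both without saturated spots). Within the slide alone they gave 0.0332 and 0.0212, and cell division 0.0159. SMc00646 fell by 0.58 ± 0.18 but was at 0.13 with median centring. Median centring moved the median of all genes by -0.25 in this contrast. SMc01043 rose by 0.51 ± 0.14, and SMc02140, at 0.74 ± 0.48, did not pass. With outlier spots kept, SMc03037 rose by 3.04 ± 0.46, and SMc00654 and SMc02146 did not pass (adjusted p = 0.0578 and 0.779).

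Chromosomal genes rose as a set (adjusted p = 8.08e-06, median 0.17), with 1281 up and 750 down, and 1295 and 760 adjusted over the list alone. Those of pSymB fell (adjusted p = 0.000136, median -0.14), with 196 up and 535 down, and 194 and 526 adjusted over the list alone. Within the slide alone the adjusted p values were 9.03e-06 and 0.000184. The fall of pSymA (adjusted p = 0.0383; 132 up and 330 down, 114 and 309 adjusted over the list alone; 0.0212 within the slide alone) gave an adjusted p = 0.0787 with an estimated correlation, 0.0829 without saturated spots and 0.208 on complete genes. Both samples also differed in medium.

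From 40 to 120 min, within the released course, SMc03004 to SMc03057 was the longest run of tags that rose at least 2-fold. Its 54 tags, all past the threshold because they were picked so in this contrast, include 30 without saturation, with a median of 3.30 on the log2 scale. Inside it SMc03025 rose by 5.61 ± 0.31 (SE, n = 4; adjusted p = 1.06e-13), or 48.9-fold, and SMc03030 by 5.34 ± 0.36. SMb21373 fell by 4.71 ± 0.63 and SMb21372 fell by 2.98 ± 0.47 (SE, n = 4). Cy3 was saturated for SMc03030 and SMc03046 on 2 of 4 arrays at 120 min, and for SMb21373 on 2 and SMb21372 on 3 of 4 at 40 min, so these sizes may be understated. All 3 motility regulators rose, SMc03046 by 3.54 ± 0.23, SMc03016 by 1.62 ± 0.19 and SMc03015 by 1.21 ± 0.19, while no size is given for the flagella tag SMc03037, whose Cy5 was saturated on every array of both time points. Of the cell division tags SMc01874 rose by 2.32 ± 0.16 and SMb21524 by 2.31 ± 0.26. With Cy3 saturated on every array at 120 min, and Cy5 on 3 of 4 at 40 min, SMb21523 was at least 2.86-fold higher (adjusted p = 0.000157). SMb21522 was saturated in both channels at 120 min.

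Among 12 regulators 7 rose and 0 fell, led by SMc02230 with 3.17 ± 0.22, SMc00021 with 2.48 ± 0.21 and SMc02369 with 2.06 ± 0.20. The 7 include SMc00654, which was saturated in both channels at 120 min and has no level there. Adjusted over the list alone 8 regulators rose and 1 fell, and 5 cell division tags and 3 motility regulators rose. Regulators, cell division and motility regulators rose as sets (adjusted p = 0.001, 0.000124 and 0.000124), and held with an estimated correlation (0.0117 each) and within the slide alone (0.00392, 0.000432 and 0.000447). On complete genes, where 2 cell division tags are left, that list gave 0.0544. The set test was down for pSymB (adjusted p = 0.0484; 238 rose and 297 fell, 245 and 305 adjusted over the list alone; 0.0439 within the slide alone), but 0.0597 without saturated spots, 0.0623 on complete genes, 0.0517 with the scanner's processed signals and 0.128 with median centring. The chromosome (adjusted p = 0.431) had a median of -0.01, a mean of 0.10 and a test pointing up, and 550 rose and 402 fell (545 and 399 adjusted over the list alone). For pSymA 243 rose and 123 fell (242 and 121 adjusted over the list alone; adjusted p = 0.244). SMc01043 fell by 0.46 ± 0.13 (adjusted p = 0.0652 without replicate 4 of 40 min, 0.0601 with offset 0 and 0.0501 in the deposited series values), and SMc01506, SMc02140, SMc00646 and SMc03873 did not pass (adjusted p = 0.11, 0.748, 0.151 and 0.0503). For SMc02146 Cy5 was saturated on every array. Of 6142 genes 1031 rose and 822 fell, 1625 passed within the slide alone, and 936 with the scanner's processed signals.

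From 60 to 140 min, on other arrays of another slide, the stretch SMc03004 to SMc03057 rose at 33 of the 36 tags without saturation, with a median of 2.57 on the log2 scale. Inside it SMc03009 rose by 4.00 ± 0.27 (SE, n = 4; adjusted p = 1.47e-11), or 15.9-fold, and SMc03006 by 3.98 ± 0.40. SMb21273 fell by 2.71 ± 0.47 and SMb21276 fell by 2.69 ± 0.36, with arrays far apart at 140 min, at 0.22 ± 1.74 and 0.17 ± 1.35 (SD, n = 4). Cy3 was saturated for SMc03009 on 1 of 4 arrays at 140 min and for SMb21273 on 3 of 4 at 60 min. Of the cell division tags SMb21524 rose by 1.96 ± 0.26. With Cy3 saturated on every array at 140 min, SMc01874 was at least 4.85-fold, SMb21522 at least 2.44-fold and SMb21523 at least 2.15-fold higher (adjusted p = 6.79e-12, 0.000455 and 0.00481). The flagella tag SMc03037, saturated likewise, was at least 6.97-fold higher (adjusted p = 3.15e-05), and SMc04296 was saturated at 60 min. SMc03046 rose by 2.16 ± 0.23, and the other 2 motility regulators, SMc03015 at 0.33 ± 0.19 and SMc03016 at 0.29 ± 0.19, did not pass.

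Among 12 regulators 6 rose and 1 fell: SMc02230 rose by 3.12 ± 0.22, SMc00021 by 2.62 ± 0.21 and SMc00059 by 2.29 ± 0.35, and SMc02139 fell by 0.95 ± 0.20. Adjusted over the list alone 6 regulators rose and 2 fell, and 4 cell division tags and 1 motility regulator rose. Regulators and cell division rose as sets (adjusted p = 0.00157 and 0.000364; with an estimated correlation 0.0252 for both; within the slide alone 0.0102 and 0.00947), though cell division gave 0.228 on complete genes. The motility regulators rose as a set (adjusted p = 0.045), with an adjusted p = 0.178 with an estimated correlation, 0.0766 within the slide alone and 0.0717 with the scanner's processed signals. None of the replicons passed, though with median centring the chromosome (down, adjusted p = 0.0284) and pSymA (up, adjusted p = 0.0035) did. The chromosome (adjusted p = 0.49) had a mean of 0.06, a median of -0.04 and a test pointing down, with 386 up and 361 down (387 and 362 adjusted over the list alone). For pSymA 144 rose and 74 fell (134 and 66 adjusted over the list alone; adjusted p = 0.0855), and for pSymB 205 rose and 191 fell (209 and 196 adjusted over the list alone; adjusted p = 0.545). SMc03873 fell by 0.57 ± 0.18, but 7 of 21 alternatives ended the call, among them Cy3 alone, at -0.29 (adjusted p = 0.449), and leaving out replicate 1 or 3 of 60 min or 4 of 140 min (adjusted p = 0.0588, 0.0523 and 0.0909). SMc01506, SMc02140, SMc00646 and SMc01043 did not pass (adjusted p = 0.786, 0.967, 0.919 and 0.484). SMc02146 was saturated on every array. Of 6142 genes 735 rose and 626 fell, 1474 passed within the slide alone, and 760 with the scanner's processed signals.

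The 2 contrasts from early to late share no arrays but share the order of slide positions. Of 6142 genes, 538 rose in both and 311 fell in both, where independent lists of these sizes would share 123 and 83.8, and 20 moved in opposite directions. Across genes, which are not independent replicates, their log2 changes correlated with Pearson r = 0.767 and Spearman rho = 0.610.

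From 80 to 100 min, both in S phase, most of the change in the ratio lay in the Cy5 reference and not in the synchronized samples. In Cy3 alone 86 genes passed, 74 up and 12 down, and 23 of them passed in the same direction among the 602 of the ratio. The stretch SMc03004 to SMc03057 rose at 23 of 53 tags by the ratio (median 0.80), and in Cy3 alone 52 of 53 were higher, 30 past the threshold (median 1.22). Inside it SMc03030 rose by 1.88 ± 0.39 and SMc03022 by 1.64 ± 0.29 (SE, 3 against 4 arrays). SMc00987 fell by 1.35 ± 0.29 and SMc02862 fell by 1.28 ± 0.34 by the ratio (SE, n = 4), but they were at -0.09 and -0.19 in Cy3 alone (adjusted p = 0.978 and 0.987). Without replicate 3 of 100 min SMc02862 gave an adjusted p of 0.0579, and in Cy3 alone SMc03030 gave 0.0584. SMc00987 gave 0.252 with outlier spots kept and 0.0883 in the deposited series values.

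By the ratio 236 of 6047 genes rose and 366 fell, and 606 passed within the slide alone. Without replicate 1 or 3 of 100 min the count was 364 or 345. All 3 motility regulators rose, SMc03046 by 1.14 ± 0.23, and of the cell division tags SMc01874 rose by 0.81 ± 0.20, with the same 3 and 1 adjusted over the list alone. SMc01874 did not pass without replicate 1 of 100 min (adjusted p = 0.133), and SMc03015 and SMc03016 lost the call when any of 3 and of 6 of the 8 arrays was left out (adjusted p up to 0.0621 and 0.152). In Cy3 alone these lists averaged 0.76 and 0.50, with 1 and 0 tags past the threshold. Both passed as sets by the ratio (adjusted p = 0.00263 and 0.00285; within the slide alone 0.00271 and 0.00244), with an adjusted p = 0.0786 for both with an estimated correlation, and cell division gave 0.278 on complete genes and 0.579 on the 1 tag left without saturated spots. Of 12 regulators SMc02369 rose by 0.85 ± 0.20 (adjusted p = 0.0884 in Cy3 alone) and SMc00776 by 0.64 ± 0.19, though the latter was at -0.24 in Cy3 alone and did not pass when any of 4 of the 8 arrays was left out (adjusted p from 0.0989 to 0.135). Adjusted over the list alone 3 regulators rose (set test, adjusted p = 0.354). No replicon passed (adjusted p = 0.347, 0.26 and 0.833 for the chromosome, pSymA and pSymB): 186 chromosomal genes rose and 287 fell (223 and 341 adjusted over the list alone), 21 and 28 on pSymA (12 and 13 adjusted over the list alone) and 29 and 51 on pSymB (21 and 32 adjusted over the list alone). For pSymB the mean was -0.01 and the median 0.01, with the test pointing up. With median centring all of them passed, the chromosome down (adjusted p = 1.94e-08), and pSymA and pSymB up (adjusted p = 9.2e-08 and 0.015). SMc03037, SMc01506, SMc02140, SMc00646, SMc03873 and SMc01043 did not pass (adjusted p = 0.864, 0.971, 0.517, 0.257, 0.165 and 0.767), nor did SMc02146 with outlier spots kept (0.166).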

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

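The regroupings of the arrays were planned before their results were seen. The tests of slide position, of the Cy5 channel, of saturated spots and of slide brightness were chosen only after the counts they bear on were seen.

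No other assignment of arrays that was tried gave as many genes as the real one, for the F-tests and the contrasts between time points. The counts against the reference were not regrouped. Each time point lies on 1 slide and in 1 row of it, so an effect of slide or row would also favour the real grouping. The regroupings therefore cannot tell such an effect from time. Only 1 of 100 regroupings, the real one, gave as many genes over the 8 time points (5565, highest other 368) or over the 7 released ones (5007, highest other 637). Of the 35 splits of each contrast, only the real 1 gave as many: 4265 against at most 1732 for 40 min and G1 arrest, 3224 against 2636 for 160 min and G1 arrest, 1853 against 638 for 120 and 40 min, 1361 against 107 for 140 and 60 min, and 602 against 58 for 100 and 80 min.

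A set of 849 genes, with most of the stretch SMc03004 to SMc03057, moved the same way from 40 to 120 min and from 60 to 140 min. The Cy5 reference carried a median of 0% of the change on both slides, with upper quartiles of 2.98% and 6.59%, and without saturated spots 98.7% of the genes with a value passed both contrasts (780 of 790). Slide position (row 2 against row 1) stays open: these genes moved in their direction by a median of 0.11 (upper quartile 0.34) from 80 to 100 min and of 0.27 (0.84) from G1 arrest to 160 min, where the lower quartile of the pattern was 0.49. With the scanner's processed signals the upper quartile from 80 to 100 min was 0.714 against 0.53, so position and a change from early to late cannot be told apart here. Progress through the cycle and time since the change of medium were not separated by any sample and stay open too.

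The 4265 genes that differed between 40 min and G1 arrest were measured on a bright and a dim slide. Genes picked with G1 arrest replicates 1 and 2 alone moved in the same direction on the slide of G1 arrest itself, from replicates 3 and 4 to 160 min, by a median of 0.53 (lower quartile 0.04), against 0.94 in the picking contrast. Of them 76.9% kept their direction, so brightness alone could not give the pattern as a whole. How far it adds to single genes stays open, as does the change of medium, which is a difference of the design.

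The 602 genes of 100 against 80 min may mostly reflect a difference in the Cy5 channel, which should be the same RNA on all arrays. Cy5 carried a median of 98.1% of their change (lower quartile 78.6%), and by channel 949 genes differed in Cy5 and 121 in Cy3. This check by channel is apart from the fit of Cy3 alone, which gave 86 genes. Median Cy5 signals on that slide were 98 to 149 over a background of 59 to 62. For 160 min and G1 arrest, on the slide of the same scan day, 0 genes differed in Cy5 and 3566 in Cy3. The SD across genes of the Cy5 difference was still 0.298 there, against 0.444 for 100 against 80 min. It was 0.133 for 120 against 40 min, with 51 genes differing in Cy5, and 0.103 for 140 against 60 min, with 1. So the 0 genes do not show that the reference was the same on the arrays of 160 min and G1 arrest. A biological change between the time points stays open for the genes that also passed in Cy3 alone.

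Among 91 sets of 4 arrays tested for 1 array apart from the rest, 6 were found, and chance gives about 4.55. The gap as a share of the range was 0.905 for the chromosome's mean at 80 min (replicate 3 high, -0.03 against -0.04 in the others) and 0.836 at 140 min (replicate 4 low, at -0.03). It was 0.948 for the mean of pSymA at 60 min, where replicate 4 was low (-0.01 against 0.01 in the others), and 0.855 for pSymA at 120 min, where replicate 3 was high (0.10 against 0.03 to 0.04). For SMc01916 to SMc01931 at 40 min it was 0.890, with replicate 2 at 0.38 and the others from 0.53 to 0.55. For the stretch SMa1808 to SMa1821 at 40 min it was 0.955, with replicate 3 at 1.87 and the others at 1.51 or below.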

How the results depend on the processing

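Saturated spots, outlier spots, Cy3 alone, bright or dim slides alone, complete genes, lists within a slide and lists without saturated spots were alternatives added after seeing the data. On the dim slides Cy5 lay close to background, which limits ratios there. The dim-gene filter removes no gene, each gene has 1 probe and Aquantile changed no ratio (largest change 0), so these change nothing by construction. Slide as a random block could not be fitted, since each time point lies on 1 slide. As a fixed block it changes no contrast within a slide and has no estimate for the others. The joint test of the within-slide contrasts between released time points gave 2584. The only-arrays-compared fit is the reported one for 8 time points. Causes were not tested unless fewer genes or a stricter threshold explain the value.

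With at least 2-fold required, the counts were 3376 over 8 time points, 2029 over the released ones, 1926, 1485, 435, 387 and 58 for the 5 contrasts in the report's order, and 1472, 964, 511, 482, 476, 556, 150 and 250 from G1 arrest to 160 min against the reference. Testing only genes bright on every array gave 3233, 2899, 2606 (40 min against G1 arrest), 968 (120 against 40), 806 (140 against 60), and 2174, 1875, 2015 and 1299 for 40, 60, 120 and 140 min against the reference. An adjusted p under 0.01 gave 219 for 100 against 80 min and 1629 for 140 min against the reference. For 120 against 40, 140 against 60 and 100 against 80 min, offset 0 gave 1014, 795 and 1103, the scanner's processed signals 936, 760 and 940, the deposited series values gave 1107, 890 and 988, and array weights 2849, 2198 and 1027. For 140 and 160 min against the reference these were 1360 and 2350 (offset 0), 1377 and 3002 (processed) and 1551 and 2745 (series table). Median centring gave 4830, 4271 and 4885 for 80, 100 and 160 min against the reference. Cy3 alone gave 86 for 100 against 80 min.

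Leaving out each array gave 345 to 654 genes for 100 against 80 min (364 without replicate 1 of 100 min, 345 without replicate 3) and 962 to 1180 for 160 min against the reference (962 without replicate 2), and moved no other count by over 1.5 times. The share of higher genes moved by over 10 points for 160 min against G1 arrest (63.6% on bright genes, 49.9% as reported), for 100 against 80 min (17.7% with median centring, 52.0% with outlier spots kept, 86.0% in Cy3 alone, 39.2% as reported) and for G1 arrest against the reference (34.4% on bright genes).

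Of 36 list tests 17 passed: 12 with an estimated correlation, 30 by fry, which does not compare a list with other genes, 19 with median centring (13 of the 17), 20 with processed signals (15 of the 17), 11 on complete genes (9 of the 17) and 14 without saturated spots (11 of the 17). The chromosome at 40 min against G1 arrest turned down with median centring (adjusted p = 0.969). By peak time, with saturated genes included, processed signals gave 1842 (G1 arrest), 716 (80 min), 352 (100 min) and 529 (160 min), median centring 608 (40 min), 855 (80 min) and 900 (160 min), and an amplitude of 1.5-fold 662, 599, 443 and 625 (40, 60, 80 and 120 min). For 78 pairs of a named gene and a contrast, 1503 of 1588 values kept direction and call, 82 lost the call and 3 changed sign: SMc00776 at -0.24 (100 against 80 min, Cy3 alone), SMc00646 at 0.13 (160 min against G1 arrest, median centring) and SMc03046 at 0.36 (40 min against G1 arrest, processed). On the log2 scale 56 values in 30 of the 78 pairs moved by over 1.5 times, 14 with median centring, 10 with processed signals, 10 in Cy3 alone, 9 in the series table and 7 with offset 0. Calls counted in the report without a size also ended when 1 array was left out: SMb21523 and SMb21524 at 40 min against G1 arrest (2 and 4 of 8 arrays), SMb21524, SMc01371 and SMc01874 at 160 min against G1 arrest (1, 4 and 2 of 7), and SMc01371 from 40 to 120 min (4 of 8).

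The replicate numbers, which are also the slide columns, were not used as pairs in the reported fits. Of 19 same-numbered pairs in the contrasts 8 correlated above 0.1, from -0.103 to 0.638. The highest were 0.638 and 0.486 for 140 against 60 min and 0.448 for 120 against 40 min, so some arrays shared a signal by number. A replicate block ended the calls of SMc03016 for 100 against 80 min and SMc01371 for 160 min against G1 arrest (adjusted p = 0.0517 and 0.0623). With a replicate block the counts were 5560 and 5011 over the course, 4282, 3199, 1878, 1394 and 625 for the contrasts, and 4094, 4037, 3324, 2627, 2571, 3759, 2478 and 1450 against the reference, and 16 lists passed, without pSymB from 40 to 120 min (adjusted p = 0.0504).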

Other observations

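The correlation test of neighbouring tags and the stretches named here were chosen only after runs of consecutive tags had been seen, so that all tags of a stretch pass by selection in the contrast it was picked in. Further stretches had a time course of their own. SMb21272 to SMb21278, over its 5 tags without saturation, averaged -0.30 at G1 arrest, 2.90 at 40 min, 3.07 at 60 min and 2.04 at 120 min, and was at 0.44 ± 1.45 (SD, n = 4) at 140 min, with arrays far apart, and at 0.16 at 160 min. SMc01790 to SMc01796 (picked from 60 to 140 min, median 2.05 over 6 tags without saturation) fell at all 7 tags from G1 arrest to 40 min (median -1.56) and rose at all 6 without saturation from 40 to 120 min (median 1.17). SMc01916 to SMc01931, picked at 40 min against G1 arrest, where 6 of its 16 tags were without saturation, also rose at all 16 tags from G1 arrest to 160 min, with a median of 2.05. Both contrasts use the same G1 arrest arrays, so this rise is favoured by the choice. Against the reference its median at 160 min was 0.19, with 5 tags higher and 2 lower.

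The stretch SMb21372 to SMb21377 (6 tags) was picked for its fall from 40 to 120 min. Cy3 was saturated on every array at 40 min for 4 of the 6, and the other 2 had a median of -3.84. All 6 fell from 60 to 140 min (median -2.49), but the arrays were far apart at 60 min, with SMb21373 at 0.52 ± 2.52 (SD, n = 4).

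Tags with neighbouring numbers may share a signal over the course, as a hypothesis, for which the tag number stands in for the place in the genome. Over 4199 pairs of neighbouring tags without saturation the median correlation of the 8 time-point means was 0.417, and over all 4878 pairs it was 0.425. In 100 sets of as many random pairs without saturation the median lay between -0.0335 and 0.0293. The longest run of tags past the threshold and at least 2-fold higher was 54 from 40 to 120 min, where 1000 permutations of the tags gave at most 5, and the longest lower run was 41 at 160 min against G1 arrest, where they gave at most 7. Spots printed near each other were not examined, and no operon table was used here.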
